A study of Bos taurus with 26 samples.

How the data were processed

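Messenger RNA was sequenced from 2 tissues of Holstein cows of a high-fertility line (Fert+) and a low-fertility line (Fert-), sampled on day 13 of the oestrous cycle. There were 14 endometrium libraries (8 Fert+ and 6 Fert-) and 12 corpus luteum libraries (7 Fert+ and 5 Fert-). The labels give each library a batch number from 1 to 4 and the cow's parity. The labels do not say that each library came from a separate cow, so the p-values measure the spread between these samples. They also do not tie endometrium and corpus luteum libraries of one cow together, so the tissues were treated as unpaired. Each of the 12 corpus luteum libraries has an endometrium library of the same line, batch and parity, and for 9 of them one such library has a number lower by 14, so both tissues may come from the same cows. The tissue contrast, the test of the tissue difference and the overlap between tissues treat the libraries as independent, and their p-values would not hold as given if cows were shared.

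Per the labels' protocols, tissue was washed, cleared of connective tissue and frozen in liquid nitrogen, RNA was extracted with TRIzol, and libraries were made from polyadenylated RNA with the TruSeq RNA kit, which does not mark the strand. The submitters' processing notes name CASAVA 1.9, FastQC 0.10.0, Trim Galore, STAR 2.3.0 and featureCounts, and the genome build UMD3.1. The annotation release, the strand setting and the handling of multiply mapped reads are not given in the sources used here, so values of overlapping, antisense or near-identical genes are uncertain. Each deposited file holds whole-number read counts for 24616 gene IDs in the same order, not normalised. The counts were used as deposited, and no library in the files was left out of the planned comparisons. The numbers of the corpus luteum libraries have gaps between 15 and 28, so it cannot be excluded that libraries are missing from the files. Of the IDs, 4236 (17.2%) had no count in any library.

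The files hold gene IDs without symbols. None of the 24616 IDs matched the gene name table used here (0 matches, assembly ARS-UCD2.0), whose cattle genes carry no IDs of this kind. The 37 gene lists and the panel of known genes that had been fixed could therefore not be tested, and 0 lists were tested. No property such as GC content or length was checked either, because 0 IDs had a value. Genes were named by a rule: symbols of genes past the threshold, members of called lists and a fixed panel, and at most 2 IDs per direction and tissue for genes without a symbol. A further part would have named the 10 genes with the smallest p where fewer than 5 pass; with 0 symbols the limit on IDs was kept instead, and the 2 IDs with the smallest p in each direction are given for each tissue, with no coordinates. The 3 line comparisons with their edgeR tests, the naming rule and the gene lists were fixed before the data were examined, as were the alternatives given below without another statement.

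Analyses were run in R 4.3.3. Each tissue was fitted alone with edgeR 4.0.16: low counts were removed with filterByExpr by line, library sizes were scaled with trimmed mean of M values (TMM) factors, and a quasi-likelihood model (robust fit) with batch as a factor and line was tested with an F test, which takes both directions. Benjamini-Hochberg adjusted p under 0.05 was the threshold. A log2 fold change above 0 means higher in Fert+, and its standard error (SE) is the estimate divided by the root of the F statistic. The difference of the line effect between tissues (corpus luteum minus endometrium) was tested in one fit of all 26 libraries with batch and line terms for each tissue. Batch was tested with its coefficients together. Overlap between tissues was tested with a one-sided Fisher's exact test. Values per library are CPM (each count scaled by the library's total) with TMM scaling.

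The alternatives were RLE and upper-quartile scaling, no low-count filter, a stricter filter (mean log2 CPM of at least 1), no batch term, batch with parity, DESeq2 1.42.0, limma 3.58.1 with voom and sample quality weights, one fit of all libraries, leaving out each library in turn, an adjusted p under 0.10, and corpus luteum without batch 4. Alternatives chosen after seeing the data were fits within batches, the fit without batch as a result of its own, fits without 4 Fert+ corpus luteum libraries that lay apart, and single values per library and the tissue difference with each library left out in turn. Single values per library were compared by exact permutation (two-sided) of the line labels over all libraries of a tissue, with Benjamini-Hochberg adjustment over 11 comparisons. These permutations ignored the batch layout, in which corpus luteum batch 4 is all Fert+. Sets of tissue-restricted IDs were defined after seeing the data: at least 100 CPM on average in one tissue and a mean at least 100-fold lower in the other, which gave 17 luteal-restricted and 25 endometrium-restricted IDs. Set tests used camera with a preset correlation of 0.01, and again with the correlation estimated, and fry.

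The fits were tested on simulated data: counts were drawn from each gene's average abundance over the libraries, its dispersion and the library sizes, with 200 genes changed. The simulated counts held no batch effects and no group of libraries apart. For the tissue difference they held no difference between tissues beyond the changed genes. The rates below therefore need not hold for the real libraries. In the endometrium simulation (14243 IDs) the edgeR fit recovered 73.7% of the genes changed 2-fold and 97% of those changed 4-fold, with 7 false calls among 177. In the corpus luteum simulation (13462 IDs) it recovered 60.6% and 96%, with 5 false calls among 161. DESeq2 gave 41 false calls among 220 in the endometrium simulation and 32 among 207 in the corpus luteum simulation. For the tissue difference (14968 IDs) edgeR recovered 46% of 2-fold and 80% of 4-fold changes. Library totals were 9627378 to 18008417 counts.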

Results

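The transcriptomes of endometrium and corpus luteum were measured by RNA sequencing in Holstein cows of a high-fertility line (Fert+) and a low-fertility line (Fert-) on day 13 of the oestrous cycle, when the corpus luteum secretes progesterone. The endometrium samples were 8 Fert+ and 6 Fert- libraries, and the corpus luteum samples were 7 Fert+ and 5 Fert- libraries. Total counts per library averaged 13220581 ± 2021911 (SD, n = 14) in endometrium and 14789717 ± 2465544 (SD, n = 12) in corpus luteum. They ranged from 9627378 to 18008417 over all 26 libraries. Totals did not differ between the lines beyond the spread of the libraries in endometrium (Fert+ minus Fert- difference -221674, exact permutation p = 0.847) or in corpus luteum (difference 450506, exact permutation p = 0.644). Single libraries set the size and sign of these differences: leaving out one at a time gave -965649 (without Fert- replicate 3) to 424990 (without Fert- replicate 14) in endometrium and -199998 (without Fert- replicate 28) to 1268310 (without Fert- replicate 25) in corpus luteum, with exact permutation p of 0.330 or more. Between 16748 and 17218 gene IDs had a count in each endometrium library, and between 15935 and 17325 in each corpus luteum library. The 10 most abundant IDs took 9.16% ± 1.71 (SD, n = 14) of the counts in endometrium and 17.9% ± 1.46 (SD, n = 12) in corpus luteum. No pair of libraries of one group agreed within sampling noise: chi-square per degree of freedom was at least 17.4 over 74 pairs.

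The tissues differed in most of the transcriptome. In the edgeR fit of all 26 libraries, 10861 of 14968 tested IDs differed between corpus luteum and endometrium at adjusted p under 0.05, of which 4979 were higher in corpus luteum and 5882 were higher in endometrium. A set of 17 IDs was picked as nearly restricted to corpus luteum, so its low share in endometrium follows from the choice. It took 4.10% ± 1.06 (SD, n = 12) of the corpus luteum counts and 0.0110% ± 0.00182 (SD, n = 14) of the endometrium counts. A set of 25 IDs picked in the same way for endometrium took 1.40% ± 0.331 (SD, n = 14) of the endometrium counts and 0.00354% ± 0.00204 (SD, n = 12) of the corpus luteum counts. The lowest share of a library in the set of its own labelled tissue was 1.47% in corpus luteum and 0.755% in endometrium.

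The first comparison asked which endometrial transcripts differ between the fertility lines. The median absolute log2 fold change was 0.10 with a median SE of 0.15, and 143 of 14243 tested IDs had an absolute log2 fold change above 1. No ID passed the threshold: edgeR called 0 genes (lowest adjusted p 0.674), with 428 IDs at an unadjusted p under 0.05 where a uniform distribution gives 712. That number was 887 without Fert+ replicate 10 and 257 without Fert- replicate 14. limma-voom called 0 as well, and DESeq2 called 8 IDs, 3 higher and 5 lower in Fert+. All 8 lay at an unadjusted p under 0.05 in edgeR, where their lowest adjusted p was 0.674. Within batch 1 and within batch 3, the batches with at least 2 libraries of each line, edgeR called 0 IDs. The batch number itself separated 8 IDs in endometrium.

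The 2 endometrial IDs with the smallest p in each direction did not pass the test, and their values are given as such. ENSBTAG00000022570 had a log2 fold change of -1.81 (SE 0.29, adjusted p = 0.674), with 0.870 CPM ± 0.369 (SD, n = 8) in Fert+ and 3.66 CPM ± 2.32 (SD, n = 6) in Fert-. Its Fert- libraries spread from 1.34 to 6.67 CPM, and its highest Fert+ library was at 1.43 CPM. ENSBTAG00000009421 had a log2 fold change of -1.15 (SE 0.25, adjusted p = 0.981), with 1.60 CPM ± 0.785 (SD, n = 8) in Fert+ and 3.34 CPM ± 1.16 (SD, n = 6) in Fert-. ENSBTAG00000017716 was at 2.34 CPM ± 0.647 (SD, n = 8) in Fert+ and 1.12 CPM ± 0.455 (SD, n = 6) in Fert- (log2 fold change 1.19, SE 0.25, adjusted p = 0.981). ENSBTAG00000013689 was at 9.89 CPM ± 3.02 (SD, n = 8) in Fert+ and 5.25 CPM ± 0.689 (SD, n = 6) in Fert- (log2 fold change 0.87, SE 0.19, adjusted p = 0.981). Its lowest Fert+ library, at 6.61 CPM, lay above its highest Fert- library, at 5.96 CPM. In all 4 batches the lines differed in the same direction for each of these IDs. Chance gives this for 12.5% of IDs and separates 8 from 6 libraries for 0.0666%, and these IDs were picked for small p among 14243 in a fit with batch, so both follow largely from the choice. In endometrium batch 4 the parity was 3 in both Fert+ libraries and 2 in the Fert- library. DESeq2 called 3 of these 4 IDs: ENSBTAG00000022570, ENSBTAG00000009421 and ENSBTAG00000013689.

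The second comparison asked the same of corpus luteum. The median absolute log2 fold change was 0.24 with a median SE of 0.18, against 0.10 and 0.15 in endometrium, a difference that was not tested, and 612 of 13462 tested IDs lay above 1. With batch in the model edgeR called 0 genes (lowest adjusted p 0.212), while 2845 IDs lay at an unadjusted p under 0.05 where a uniform distribution gives 673. Of these, 1632 were higher and 1213 lower in Fert+. The 2845 also depended on single libraries: it was 1539 without Fert+ replicate 16 and 4373 without Fert+ replicate 23. It was 1104 without Fert- replicate 17 and 1105 without Fert+ replicate 19. Replicates 17 and 19 are the only libraries of batch 2, so with batch in the model leaving out either removes the same line contrast. limma-voom called 0 IDs and DESeq2 called 195, of which 70 were higher and 125 lower in Fert+. With batch in the model 0 IDs differed between batches. With 12 libraries in 4 batches, this does not exclude batch differences. Without batch in the model edgeR called 1191 IDs, 624 higher and 567 lower. These calls lay close to the threshold (lowest adjusted p 0.0475): leaving out any one of Fert+ replicates 15, 16, 18 or 19 or Fert- replicates 17, 25 or 28 gave 0. Without Fert- replicate 27 there was 1 call, without Fert- replicate 20 there were 464, and without Fert+ replicates 21, 24 or 23 there were 1842, 2171 or 3241. The one fit of all 26 libraries called 259 IDs in corpus luteum, and leaving out Fert+ replicate 23 in the fit with batch gave 908 calls. Within batch 1 and within batch 3 edgeR called 0 IDs (1338 and 363 at an unadjusted p under 0.05). In corpus luteum batch 1 both Fert+ libraries were of parity 2 and both Fert- libraries of parity 4, so values within that batch do not separate line from parity. Batch 2 held 1 library of each line. Batch 4 held Fert+ replicates 15 and 18 alone. With batch in the model these libraries entered the spread but not the line contrast, and without batch they entered both.

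**Figure D1:**
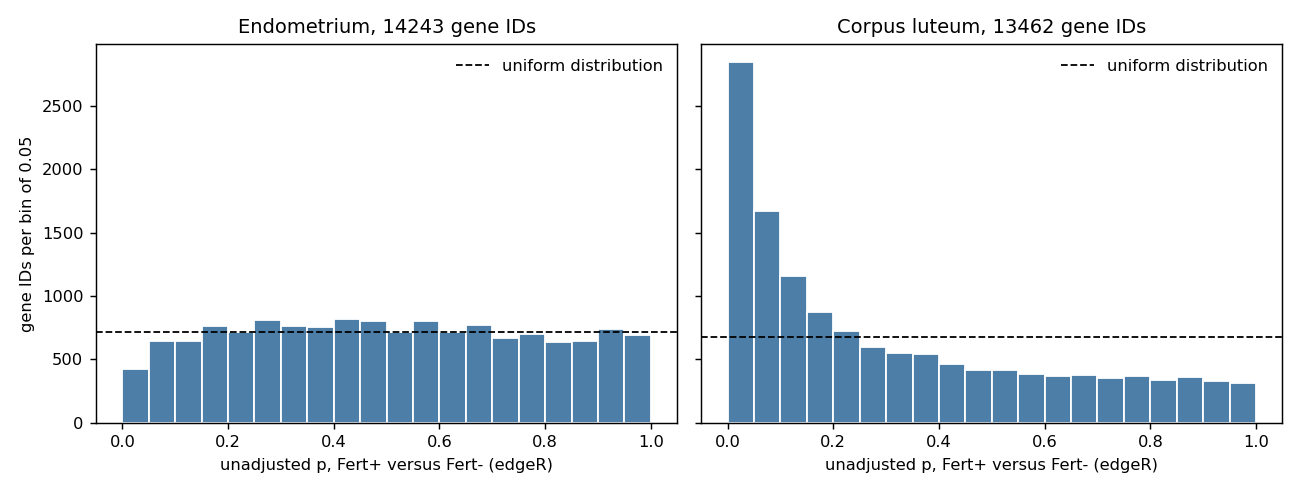
Histograms of the unadjusted edgeR p-values of Fert+ against Fert- over all tested gene IDs, in bins of 0.05, for endometrium (14243 IDs) and corpus luteum (13462 IDs). The dashed line is the uniform expectation; the lowest bin holds 428 IDs in endometrium and 2845 in corpus luteum.

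The corpus luteum libraries did not form one cloud within the Fert+ line. On the first principal component (39.4% of the variance), Fert+ replicates 15, 16, 18 and 19 scored 48.2, 51.6, 50.8 and 47.7. The other Fert+ replicates, 21, 23 and 24, scored -8.19, -22.9 and -8.47, beside Fert- replicates 17, 20, 25, 27 and 28 at -44.0, -21.5, -27.8, -19.6 and -45.9. The score averaged 22.7 ± 33.9 (SD, n = 7) in Fert+ and -31.8 ± 12.4 (SD, n = 5) in Fert- (exact permutation p = 0.0114, adjusted p = 0.118). Within batches 1, 2 and 3 the lines differed by 25.3, 91.8 and 38.1. Without these 4 libraries, an alternative chosen after seeing the data, the difference was 18.6 (exact permutation p = 0.125) and edgeR called 0 IDs with batch in the model (519 at an unadjusted p under 0.05) and 0 without it (700). Of the 1191 IDs called without batch, 1173 were still tested with 3 against 5 libraries; 1153 of these had the same sign, 405 lay at an unadjusted p under 0.05, and the median log2 difference in the direction of the call was 0.37, against 0.76 in all 12 libraries. These 8 libraries also entered the call, so the sign agreement is not independent of it. In endometrium the first component held 26.6% of the variance, and the lines differed by 19.5 (exact permutation p = 0.226, adjusted p = 0.497), by 10.6 without Fert- replicate 14 (exact permutation p = 0.497), by 28.4 without Fert+ replicate 10 (exact permutation p = 0.0280, adjusted p = 0.103), or by 31.3, -0.569, 3.72 and 38.7 within batches 1 to 4.

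**Figure D2:**
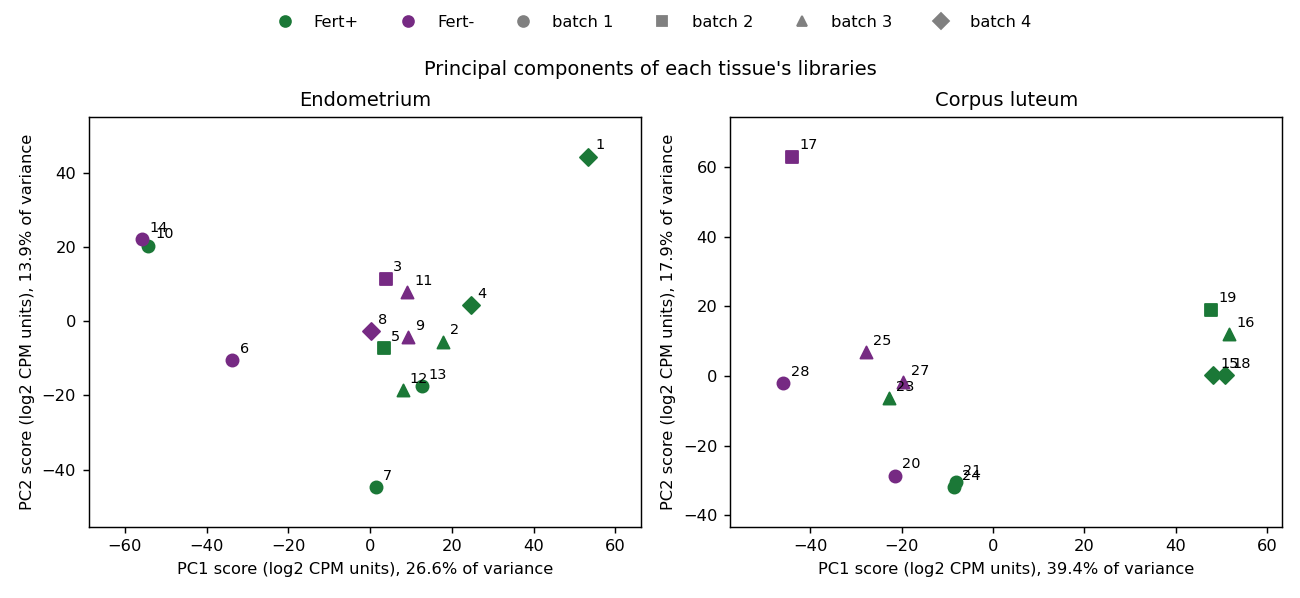
First and second principal components of log2 CPM in endometrium (left) and corpus luteum (right); each point is a library with its replicate number, colour gives the line and shape the batch. Fert+ corpus luteum replicates 15, 16, 18 and 19 lie between 47.7 and 51.6 on the first component, and every other corpus luteum library lies at -8.19 or below.

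The 200 IDs with the highest weights on that component averaged 4.23, 4.32, 4.22 and 4.24 log2 CPM in replicates 15, 16, 18 and 19. They averaged 1.49, 1.51 and 1.55 in Fert+ replicates 21, 23 and 24, and between 1.30 and 1.56 in the 5 Fert- libraries. In the 14 endometrium libraries the same IDs averaged 2.01 to 2.32. The 200 IDs with the lowest weights left the 4 close to Fert+ replicates 21 and 24: they averaged 1.79, 2.05, 1.56 and 2.07 in replicates 15, 16, 18 and 19, 2.19, 2.93 and 2.25 in replicates 21, 23 and 24, and between 2.78 and 4.62 in the Fert- libraries. Both sets were picked by their weights on this component, so they describe it and do not test it. Replicates 15, 16, 18 and 19 also had a count for 17176, 17325, 17091 and 17014 IDs, while the highest number in the other corpus luteum libraries was 16609, in Fert- replicate 17.

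The 2 corpus luteum IDs with the smallest p in each direction did not pass the threshold with batch in the model, and each of them passed it in DESeq2, in the fit without batch and without Fert+ replicate 23. ENSBTAG00000005328 was at 21.2 CPM ± 2.45 (SD, n = 7) in Fert+ and 13.1 CPM ± 1.36 (SD, n = 5) in Fert-, a log2 fold change of 0.61 (SE 0.12, adjusted p = 0.212). ENSBTAG00000026461 was at 93.5 CPM ± 29.5 (SD, n = 7) in Fert+ and 39.8 CPM ± 8.54 (SD, n = 5) in Fert-, a log2 fold change of 1.11 (SE 0.21, adjusted p = 0.212). ENSBTAG00000005868 was at 31.5 CPM ± 5.12 (SD, n = 7) in Fert+ and 51.0 CPM ± 5.29 (SD, n = 5) in Fert-, a log2 fold change of -0.62 (SE 0.11, adjusted p = 0.212). ENSBTAG00000031814 was at 2.77 CPM ± 0.671 (SD, n = 7) in Fert+ and 7.51 CPM ± 2.54 (SD, n = 5) in Fert-, a log2 fold change of -1.35 (SE 0.25, adjusted p = 0.212). For each of these IDs the values of the 7 Fert+ and 5 Fert- libraries did not overlap, replicates 21, 23 and 24 included. For ENSBTAG00000005328 the lowest Fert+ library was at 17.4 CPM and the highest Fert- library at 14.7 CPM. For ENSBTAG00000005868 the highest Fert+ library was at 37.1 CPM and the lowest Fert- library at 44.2 CPM. Chance separates 7 from 5 libraries in this way for 0.253% of IDs, and these IDs were picked for small p among 13462. In ENSBTAG00000026461, Fert+ replicates 21, 23 and 24 were at 63.9, 54.3 and 71.0 CPM, and replicates 15, 16, 18 and 19 at 108, 128, 115 and 115 CPM.

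**Figure D3:**
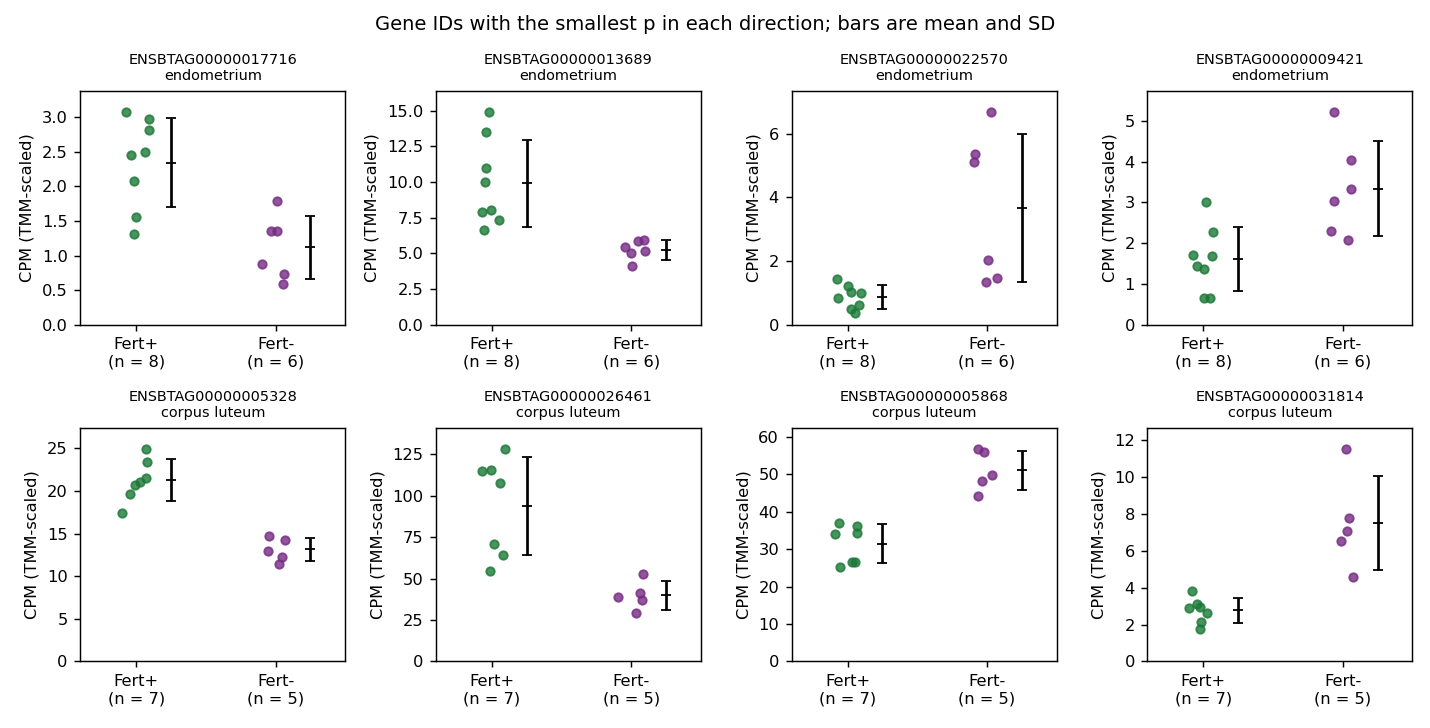
CPM per library of the 2 gene IDs with the smallest p in each direction, in endometrium (top row, Fert+ n = 8, Fert- n = 6) and corpus luteum (bottom row, Fert+ n = 7, Fert- n = 5); bars are mean and SD. In corpus luteum the lines do not overlap for any of the 4 IDs, and none of the 8 IDs passed the edgeR threshold.

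The third comparison asked whether the line effect differed between the tissues. edgeR called 0 of 14968 IDs (lowest adjusted p 0.270), with 2252 at an unadjusted p under 0.05 where a uniform distribution gives 748; DESeq2 and limma-voom also called 0. Without the 4 corpus luteum libraries apart, 599 IDs lay at an unadjusted p under 0.05. Leaving out single corpus luteum libraries gave 636 calls without Fert+ replicate 23 (3479 at an unadjusted p under 0.05) and 13 without Fert+ replicate 16 (1418). It gave 0 calls without Fert- replicate 17 (1014) and without Fert+ replicate 19 (1000). Those are the only corpus luteum libraries of batch 2, so both fits drop the same line contrast. For the 4 IDs named in corpus luteum, the luteal minus endometrial line effect on the log2 scale was -1.82 for ENSBTAG00000031814, 1.06 for ENSBTAG00000026461 and 0.75 for ENSBTAG00000005328 (adjusted p = 0.270 for each), and -0.45 for ENSBTAG00000005868 (adjusted p = 0.284). For the 4 IDs named in endometrium it was -0.87 for ENSBTAG00000017716, -0.83 for ENSBTAG00000013689, 1.34 for ENSBTAG00000022570 and -0.48 for ENSBTAG00000009421, with adjusted p of 0.274 or more.

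No ID was called in both tissues (0 of 12979 tested in both). At an unadjusted p under 0.05, 354 IDs in endometrium and 2777 in corpus luteum shared 78, where independent lists would share 75.7 (one-sided Fisher's exact test p = 0.404), and 61 of the 78 had the same sign. The test ignores direction, and the sign agreement was not tested. It also takes the tissues as independent, while the labels do not say whether libraries of both tissues came from the same cows. Across the 12979 IDs, which are not independent replicates, the log2 fold changes of the tissues had Pearson's r of 0.119 and Spearman's rho of 0.0737.

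The luteal-restricted IDs took 4.62% ± 0.497 (SD, n = 7) of the counts in Fert+ and 3.37% ± 1.25 (SD, n = 5) in Fert- corpus luteum (difference 1.25, exact permutation p = 0.0215, adjusted p = 0.118 over 11 comparisons). The difference was 2.39 within batch 1, 2.02 within batch 2 and -0.377 within batch 3, and it was 1.09 without the 4 libraries apart (exact permutation p = 0.196). Without Fert- replicate 28, which had the lowest share at 1.47%, the difference was 0.773 (exact permutation p = 0.0545, adjusted p = 0.201). The next lowest was Fert- replicate 17 at 2.99%, while Fert- replicates 25 and 27, at 4.54% and 4.44%, lay within the range of the Fert+ libraries. The endometrium-restricted IDs went the other way in corpus luteum, at 0.00258% ± 0.00123 (SD, n = 7) of the counts in Fert+ and 0.00487% ± 0.00231 (SD, n = 5) in Fert- (difference -0.00229, exact permutation p = 0.0593, adjusted p = 0.201). That difference was -0.00229, -0.00236 and -0.00176 within batches 1 to 3 and -0.00261 without the 4 libraries apart (exact permutation p = 0.161). Of the 17 luteal-restricted IDs, 13 were higher and 4 lower in Fert+, and 0 passed the edgeR threshold; camera gave p = 0.0777, or p = 0.335 with an estimated correlation, and fry p = 0.138. In endometrium, the endometrium-restricted IDs took 1.47% ± 0.312 (SD, n = 8) of the counts in Fert+ and 1.30% ± 0.358 (SD, n = 6) in Fert- (exact permutation p = 0.345). Their difference was 0.175, or 0.489, -0.285, -0.0338 and 0.371 within batches 1 to 4, and it was 0.0667 without Fert- replicate 14 and 0.264 without Fert+ replicate 7. Of these 25 IDs, 18 were higher and 7 lower in Fert+ and 0 passed; camera gave p = 0.0166, which became p = 0.255 with an estimated correlation, and fry gave p = 0.376.

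**Figure D4:**
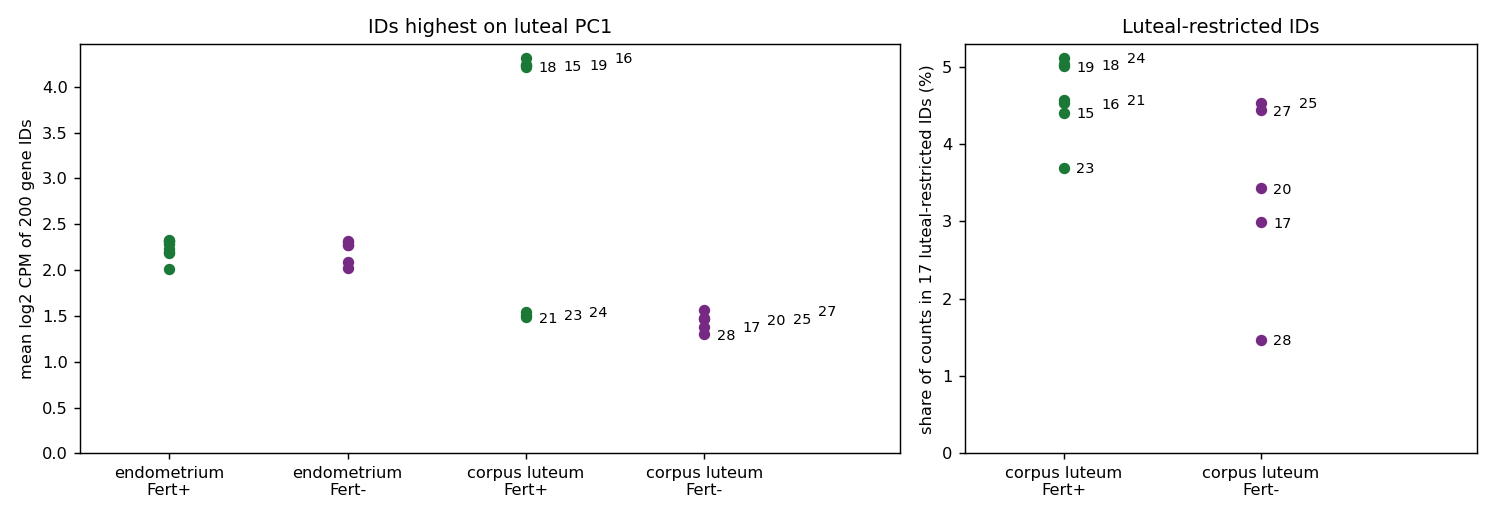
Left, mean log2 CPM of the 200 gene IDs with the highest weights on the first luteal component, one point per library in all 4 groups; right, share of counts (%) in the 17 luteal-restricted IDs in corpus luteum, with replicate numbers. Replicates 15, 16, 18 and 19 lie at 4.22 to 4.32 on the left and every other library at 2.32 or below; Fert- replicate 28 is lowest on the right at 1.47%.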

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

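The tests of batch number, depth and fertility line in this part were chosen after the result was seen. A library was set apart when its gap to the nearest library of its group was large against the group's range, which chance gives in about 1 of 20 groups; 2 of 40 groups of values met this, and 2 are expected by chance. In endometrium Fert+ replicate 1 the 10 most abundant IDs took 14.2% of the counts, and the next Fert+ library was at 10.2%. In endometrium Fert+ replicate 13 the 200 IDs of the first luteal component averaged 2.01 log2 CPM, and the next Fert+ library was at 2.18.

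Fert+ corpus luteum replicates 15, 16, 18 and 19 lay apart from the other 8 libraries on the first principal component, which drew attention as a split inside one line. Replicates 16 and 19 came from batches 3 and 2, and the 4 other libraries of these batches all lay outside the group apart. For replicate 16 this argues against the batch number of the labels as the cause, with 3 other libraries outside, Fert+ replicate 23 among them. For replicate 19 the only other library of its batch was Fert- replicate 17. With 1 library of the other line, batch cannot be told apart from line there and stays open. For replicates 15 and 18 batch cannot be told apart from line, since their batch 4 held 0 other corpus luteum libraries and Fert+ alone. Sequencing depth is argued against as well, since with every library thinned to about 11924906 counts the gap between the 4 and the nearest other library was 56.7% of the range, against 57.3% before. Fertility line alone is argued against as the whole cause of the split, because 3 of the 7 Fert+ libraries lay outside the group apart, which was set by the widest gap on the component without the labels, although a line effect on part of the pattern stays open. Parity was 3 in replicates 15, 16 and 18 and 4 in replicate 19, and every Fert+ library of parity 3 lay in the group. Outside it, Fert- replicates 25 and 27 were of parity 3. Fert+ replicate 23 and Fert- replicates 17, 20 and 28 were of parity 4, and Fert+ replicates 21 and 24 of parity 2. Parity was not tested as a cause. A difference in tissue sampling, RNA handling or library preparation that the labels do not record may also underlie the split. That stays open because no label separates the 4 libraries, and gene properties could not be checked with 0 IDs matched.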

How the results depend on the processing

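The fits within batches, the fits without the 4 Fert+ corpus luteum libraries apart, the luteal fit without batch as a result of its own, and the shares of restricted IDs and the tissue difference with single libraries left out were chosen after seeing the data. The endometrium count of 0 held under the scaling, filter, batch, parity, limma-voom, joint and 0.10 alternatives; DESeq2 gave 8, and leaving out single libraries gave 0 to 1, with 1 without Fert- replicate 8. The corpus luteum count of 0 held under both other scalings, the stricter filter, parity, limma-voom, the 0.10 threshold and without batch 4. It was also 0 within batches 1 and 3 and without the 4 libraries, but few libraries remained there, so this says little about a line effect. The count became 4 with no low-count filter, 195 with DESeq2, 259 in the fit of all 26 libraries and 1191 without batch. Leaving out single libraries gave 0 to 908: 908 without Fert+ replicate 23, 1 without Fert- replicate 20 and 1 without Fert- replicate 27. In the luteal fit without batch, the 1191 calls became 2947 with DESeq2, 5035 with limma-voom and 0 without the 4 libraries, where 3 against 5 remained, 1153 of the 1173 IDs still tested had the same sign and the median log2 difference in the direction of the call went from 0.76 to 0.37. Leaving out single libraries there gave 0 to 3241: 0 without replicate 15, 16, 17, 18, 19, 25 or 28, 1 without 27, 464 without 20, 1842 without 21, 2171 without 24 and 3241 without 23. Of the 1191 IDs, 178 were among the 195 DESeq2 calls. The tissue difference was 1 with parity in the model, and leaving out single libraries gave 0 to 636: 636 without Fert+ corpus luteum replicate 23 and 13 without Fert+ corpus luteum replicate 16. It was 0 under its other alternatives. The luteal-restricted share difference was -0.377 within batch 3, and the endometrium-restricted one -0.285 within batch 2 and -0.0338 within batch 3. Leaving out single libraries gave 0.773 (without Fert- replicate 28) to 1.54 for the first and 0.0667 (without Fert- replicate 14) to 0.264 (without Fert+ replicate 7) for the other. The 8 named IDs kept their direction in all 199 fits that tested them. They were picked for small p in the same libraries, so this follows largely from the choice. Of the 199, 18 passed the threshold, and ENSBTAG00000017716 fell below the stricter filter. The number of batch genes was 7 against 8 in endometrium and 0 in corpus luteum with RLE scaling. Apart from fits with fewer libraries, the cause was not tested. The gene list alternatives were not run because no list could be tested. No paired analysis was run, because the groups share no replicate numbers and no label links the libraries of one cow. Pairs matched by line, batch and parity were not tried. At totals of 9627378 to 18008417 counts the low-count filter left 14243 endometrial and 13462 luteal IDs of 24616, and the fit with no such filter tested 19610 and 19431.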

Other observations

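In this part, the luteal fits without batch and those without 4 Fert+ libraries were treated as results only after the data were seen. The split tests of unadjusted p, of DESeq2 calls and of the fit without batch, and the splits within batches, were chosen after the real counts were seen. Endometrium libraries also spread within a batch. Replicates 6, 10 and 14, all labelled batch 1 and parity 4, scored -33.7, -54.2 and -55.7 on the first endometrial component. Replicates 7 and 13, labelled batch 1 and parity 2, scored 1.41 and 12.6, and replicates 3, 5 and 12, of parity 4 in other batches, scored 3.93, 3.36 and 7.96. Fert+ replicate 1 was at the other end, at 53.3. In corpus luteum batch 1, Fert- replicates 20 and 28, of parity 4, scored -21.5 and -45.9, and Fert+ replicates 21 and 24, of parity 2, scored -8.19 and -8.47.

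The libraries were also split in other ways into groups of the same sizes and refitted; each count of splits includes the real one. Some splits ignore the batch layout, in which corpus luteum batch 4 is all Fert+, and others, within batches, keep the number of libraries of each line in every batch. Where the real count is 0, each of the 100 splits reaches it by construction, so these counts do not test chance: this holds for the calls in endometrium (real 0, highest other 3), for those in corpus luteum with batch (real 0, highest other 4) and for those of the tissue difference (real 0, highest other 676). In endometrium, the 428 IDs at an unadjusted p under 0.05 were reached by 72 of 100 splits (highest other 2219) and by 64 of 100 within batches (highest other 1595). The 8 DESeq2 calls were reached by 20 of 60 (highest other 312) and by 15 of 60 within batches (highest other 181), so chance is not excluded for either. These highest counts are far above the real ones; a structure of the samples other than the line may add to them, which was not tested. For the tissue difference, the 2252 IDs at an unadjusted p under 0.05 were reached by 7 of 100 splits (highest other 3369) and by 9 of 100 within batches (highest other 3493), so chance is not excluded there either.

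In corpus luteum, the 2845 IDs at an unadjusted p under 0.05 were reached by 4 of 100 splits (highest other 3581), which is just under the limit of 5 of 100. Within batches they were reached by 2 of 36 (highest other 3417), so chance is not excluded once batch is kept. With batch in the model, mirrored splits count once. The other of these splits only exchanged Fert+ replicate 23 for Fert- replicate 27, so it kept most of the real line labels. The 195 DESeq2 calls were reached by 5 of 60 splits and by 3 of 36 within batches (highest other 1321 in each). Chance is therefore not excluded for them. Within batches and up to mirroring, the others again only exchanged Fert+ replicate 23, for Fert- replicate 27 (1321 calls) or Fert- replicate 25 (379 calls). The 1191 calls without batch were reached by 4 of 100 splits (highest other 3087) and by 2 of 72 within batches (highest other 2062). Both shares are under the limit of 5 of 100. The within-batch split with 2062 calls also only exchanged Fert+ replicate 23 for Fert- replicate 27. Leaving out replicate 23 gave 908 calls with batch and 3241 in the fit without batch. The fit was treated as a result, and its split test chosen, only after the calls were seen. The shares were also not adjusted for the number of split tests, so chance is not excluded for these calls. Among the splits that place replicates 15, 16, 18 and 19 on one side, as the real one does, 4 of 10 reached 1191. Within batches 2 of 18 such splits did, and the within-batch splits that part the 4 gave 0.

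The luteal splits with high counts follow the 4 libraries apart in part. All 4 of the 100 splits without batch that reached 1191 calls placed replicates 15, 16, 18 and 19 on one side. For the 2845 IDs at an unadjusted p under 0.05, 3 of the 4 splits did so, and the exception was the highest, at 3581. For the 195 DESeq2 calls, 3 of the 5 splits did so; the exceptions had 602 and 683 calls, and 2 other splits that kept the 4 together gave 0. The fit without batch called 1191 IDs with these 4 libraries and 0 without them. The calls were close to the threshold, and leaving out any one of the 4, or Fert- replicate 17, 25 or 28, also gave 0, so the loss of calls does not single them out.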
